A study of Mus musculus with 12 samples.

How the data were processed

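Messenger RNA was measured in 12 samples from a mouse Eµ-myc B cell lymphoma line, in which the Myc oncogene is driven by an immunoglobulin heavy chain enhancer, on a C57BL/6 background. Per the labels' protocols, cells were left untreated or given recombinant mouse interferon-γ (IFN-γ) at 5 ng/mL, stimulation was stopped at different times with a neutralising antibody against IFN-γ at 50 µg/mL, and cells were collected 24 h post stimulation. Polyadenylated RNA from 500 ng of total RNA was made into stranded libraries with 10 cycles of PCR and read from both ends over 125 bp, per the labels' protocols. The labels do not say whether the 3 samples of a group came from separate cultures, whether the 24 h or the unstimulated samples also received antibody, or when unstimulated cells were collected. The p-values therefore measure only the spread between these samples, which can be technical.

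The authors deposited 1 table of raw counts per gene, and these whole-number counts were used as deposited. Per the submitters' processing notes, STAR 2.5.2a, featureCounts 1.4.3-p1, Picard and the mm10 build were used; the annotation release and the strand setting of the counting are not given in the sources used here. The header of the table doubles some separators, so its 12 sample names were matched to the 12 value columns in order and to the sample titles by exact name. Low counts were mostly even: of the genes with 1 to 20 counts, between 69.9% and 73.9% had an even count in each library. This is what results when each mate of a read pair adds 1 count, so a count is worth less than an independent molecule, and the floor used for genes at 0 was 6 counts over a group, equal to 3 read pairs. Floors and intervals cover counting error only, since PCR copies were not separated.

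The table holds 53379 gene identifiers, of which 53274 (99.8%) had a symbol in the reference table of gene names and 105 did not. Coordinates, 1-based on GRCm38 (the mm10 assembly), exon lengths and GC content came from GENCODE M21. Of the 14299 genes tested, 14281 were found there, 12759 with the same identifier version, so the authors' gene models can differ in part. Library totals ran from 49440358 to 67096610 counts. Reads of near-identical genes can be split or lost in counting, so values of the H2-Q genes, H2-K1 and H2-D1, the Tgtp1 and Tgtp2 pair, the guanylate-binding proteins and Serpina3f and Serpina3g are uncertain for the single gene; because the strand setting is not given, so are genes with an antisense partner.

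Genes were filtered with filterByExpr by group and scaled with TMM factors, and 4 groups of 3 samples were fitted together with edgeR 4.0.16 (R 4.3.3), using robust quasi-likelihood F tests with 8 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 14299 genes tested are called. Levels are in CPM, counts scaled to a common library size after TMM, given as mean ± SD with n = 3, and log2 fold changes carry an approximate standard error, the fold change divided by the square root of F. The common biological coefficient of variation was 0.0579. Pairs of samples within a group had a chi-square per degree of freedom of 2.415 to 7.882 over the genes compared, on counts halved to read pairs. Each value lies above what sampling noise alone gives on halved counts, so no library was counted as a repeat of another.

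Before the data were examined, 19 gene lists with 419 members were fixed, and so were the comparisons, the alternatives and the rule for naming genes. The lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusting over the 19 lists within a comparison. Camera sets a list against the other genes, while fry tests the list by itself. Counts of members are over those tested. A member low in unstimulated cells passed the filter only where another group expressed it, and members low in every group were left out. Shares of members called higher are therefore not shares of the whole list. The naming rule took 12 fixed genes whatever their result, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM, groups that do not overlap and a symbol that is not a predicted-gene name, and from each list the 2 called members with the largest change, or every called member where 5 or fewer were called. Results of some genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen. The alternatives were DESeq2 1.42.0 and limma-voom as other tests, RLE size factors, 2 other filters (at least 1 count in any library, or at least 1 CPM in at least 3 libraries), a fit to the 6 libraries compared, a replicate block, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and each library left out in turn. Halved counts and the removal of each library's trend on exon length or on GC content were added after seeing the data.

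Comparisons of the 3 exposures with unstimulated cells share 3 control libraries. Agreement between them was set beside 100 simulated data sets with no change in any group, drawn with the fitted spread; the controls are too few to split. On simulated counts for the comparison of 1 h with unstimulated cells, over 13882 genes tested, the procedure called 62% of genes changed 1.25-fold, 91.8% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold, and 9 of its 184 calls were false. The changed genes had a mean of at least 1 CPM, and counts followed the fitted trend of the spread. No outlying library and no length or GC trend was simulated, so these rates need not hold for the real libraries.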

Results

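RNA was sequenced from a mouse Eµ-myc B cell lymphoma line at the end of 4 treatments, with 3 samples in each: unstimulated cells, and cells exposed to IFN-γ for 1 h, 6 h or 24 h. The shorter exposures were ended with a neutralising antibody and the cells were kept until 24 h, so the data address what remains at harvest after the cytokine is blocked. Library totals were 49440358 to 67096610 counts. The first principal component held 44.15% of the variance and separated the 24 h libraries from the other 9. The second, with 7.84%, separated IFNg_6h replicate 3 from the other 11 libraries.

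After exposure for the whole 24 h, many transcripts of the IFN-γ pathway and of antigen presentation were higher than in unstimulated cells. The median fold was 1.46 over the list of receptor, signal transduction and feedback genes. It was 3.26 over MHC class I genes and 2.01 over MHC class II genes. The transcription factor Irf1 (ENSMUSG00000018899.16, chromosome 11, 53770014 to 53778374) rose from 10.6 ± 0.245 to 221.1 ± 8.92 CPM (SD, n = 3), a log2 fold change of 4.39 ± 0.06 (SE; edgeR adjusted p = 1.07e-29). Of 19 genes of the receptor, its signal transduction and its feedback, 11 rose and 0 fell (12 and 2 adjusted over the list alone; camera adjusted p = 2.61e-05 with an estimated correlation). Cd274, which encodes the checkpoint ligand PD-L1, rose from 6.14 ± 0.412 to 62.4 ± 10.5 CPM. Socs1, a feedback inhibitor of the pathway, rose from 0.382 ± 0.0189 to 8.86 ± 0.429 CPM. The receptor genes Ifngr1 and Ifngr2 had log2 fold changes of -0.15 ± 0.06 and 0.17 ± 0.07 and were not called (adjusted p = 0.102 and 0.0725). Myc stood at 1614 ± 28.6 CPM in unstimulated and 1690 ± 77.3 CPM in 24 h cells (adjusted p = 0.296). Ifng itself had between 0 and 8 counts per library and was not tested.

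Interferon-inducible GTPases, which act against intracellular pathogens, were higher in all 17 members tested after 24 h, of 22 in the list. All 17 also passed adjusted over the list alone (camera adjusted p = 1.26e-09 with an estimated correlation). Their median log2 fold change was 7.16, and it was the same with the 3 members at 0 in unstimulated cells placed at their lower bound. Gbp2 rose from 0.346 ± 0.127 to 962.1 ± 11.2 CPM. Tgtp1 had 0 counts in the unstimulated libraries and 16901 over the 24 h libraries, at least 2560-fold higher with a floor of 6 counts over the group. Iigp1 had 2 counts against 169388, a ratio of 77000 with a 95% counting interval from 13800 to 3040000.

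MHC class I presentation genes were higher in all 24 members after 24 h (24 adjusted over the list alone; camera adjusted p = 3.11e-06 with an estimated correlation). B2m, the class I light chain, rose from 310.3 ± 22.8 to 1072 ± 44.8 CPM, and Nlrc5, the transactivator of class I genes, from 32.5 ± 0.299 to 198 ± 8.47 CPM. Of 15 MHC class II genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 6.09e-05 with an estimated correlation). Ciita, the class II transactivator, rose by 1.03 ± 0.09 on the log2 scale. The member that fell was Lgmn, at -0.14 ± 0.05 (chosen after its value was seen). Antiviral genes known from type I interferon rose in 31 of 36 tested members, of 50 in the list (32 adjusted over the list alone, camera adjusted p = 2.6e-06 with an estimated correlation). Zbp1, a nucleic acid sensor, went from 0.0367 ± 0.00311 to 3.55 ± 0.407 CPM.

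**Figure D1:**
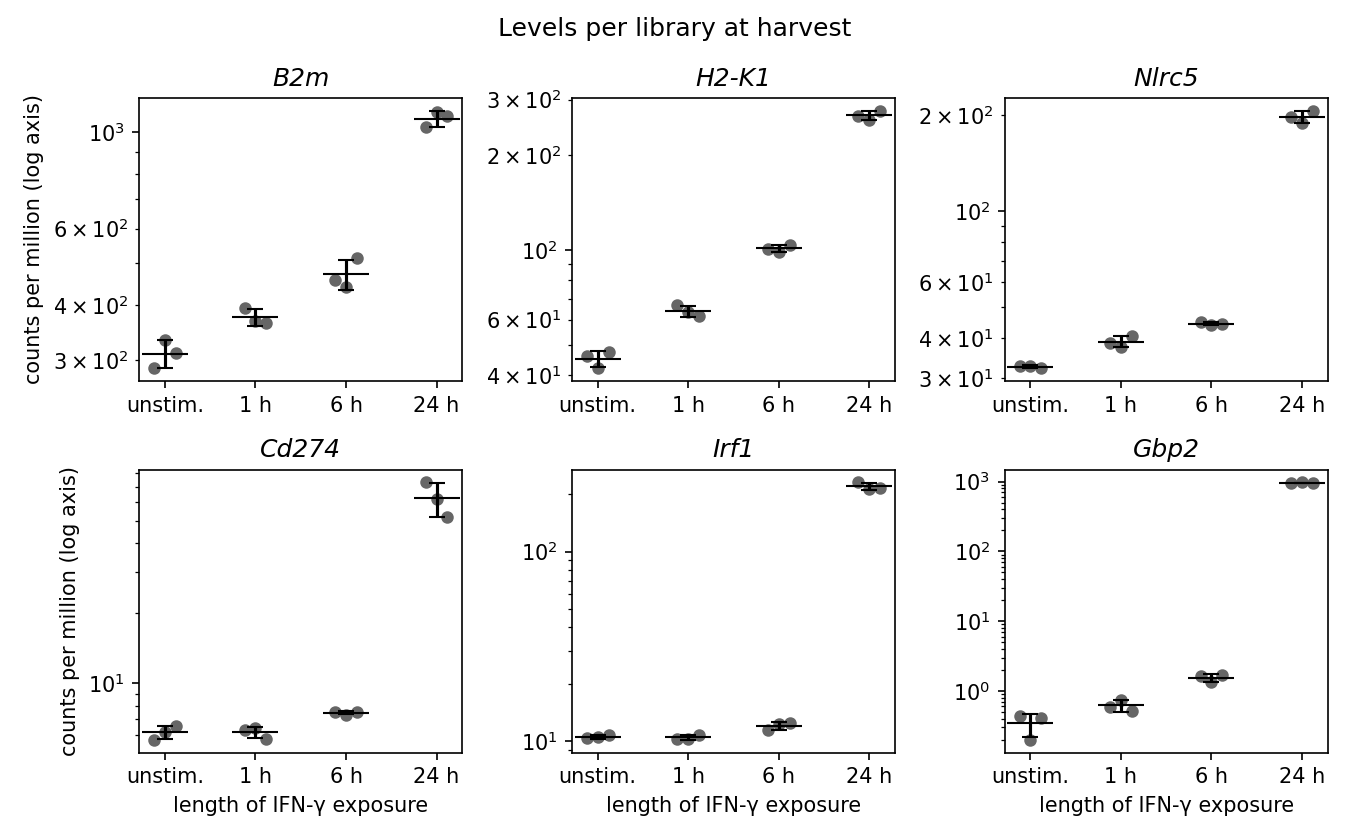
CPM on a log axis for 6 genes in each library (points), with group mean and SD (bars, n = 3), against the length of IFN-γ exposure. H2-K1 averages 45.1 CPM in unstimulated cells and 63.9, 101.0 and 267.1 CPM after 1 h, 6 h and 24 h, while Irf1 averages 10.5 to 12.1 CPM in the first 3 groups and 221.1 CPM after 24 h.

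After 24 h, checkpoint, costimulation and adhesion genes rose in 10 of 12 tested members, of 20 in the list, and fell in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.000532 with an estimated correlation). Cd86 was higher by 1.82 ± 0.24 on the log2 scale, and the 1 that fell was Cd48 (-0.24 ± 0.06, chosen after its value was seen). Cell death genes rose in 10 of 22 and fell in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.0263 with an estimated correlation). Casp4 and Mlkl, effectors of pyroptosis and necroptosis, were higher by 1.89 ± 0.28 and 1.71 ± 0.30. The 2 that fell, chosen after their values were seen, were Bcl2 (-0.51) and Casp9 (-0.22). MYC and ribosome biogenesis targets fell in 15 of 32 members and rose in 0 (18 and 1 adjusted over the list alone), by small amounts such as Srm at -0.20 ± 0.04. The camera call was lost with an estimated correlation (adjusted p = 0.324). In the p53 list 6 of 15 rose (6 adjusted over the list alone), led by Trp53inp1 at 0.94 ± 0.05 (adjusted p = 0.0761 with an estimated correlation). In the NF-κB list 7 of 14 rose (7 adjusted over the list alone), with Cflar at 0.64 ± 0.07 (adjusted p = 0.134 with an estimated correlation). B cell identity genes went both ways, 6 higher and 8 lower of 21 (6 and 9 adjusted over the list alone; camera adjusted p = 0.267), among them the repressor Bcl6 at 2.69 ± 0.32. Of 5 tested myeloid markers 2 rose (2 adjusted over the list alone; adjusted p = 0.0516 with an estimated correlation), Mpeg1 from 6.62 ± 0.571 to 40.7 ± 2.07 CPM and Fcgr3 from 0.318 ± 0.0922 to 0.908 ± 0.276 CPM. Of 2 tested T and NK markers 0 were called by edgeR (0 adjusted over the list alone). With fry, MYC targets (adjusted p = 0.000996) and B cell genes (0.0175) were called lower. The p53 list (5.26e-06), the NF-κB list (3.85e-05) and myeloid markers (5.26e-06) were called higher with fry.

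In all, 2667 of 14299 genes were called after 24 h, 1473 higher and 1194 lower, of which 310 and 71 changed at least 2-fold. Across genes, which are not independent replicates, log2 fold changes correlated with GC content (Spearman's rho = -0.197) and less with exon length (0.071). The largest named falls were Prss23 (-1.96 ± 0.24), Pdzd2 (-1.88 ± 0.25) and Fcmr, the receptor for IgM (-1.72 ± 0.16). Igll1, a surrogate light chain of precursor B cells, fell from 26.9 ± 2.32 to 10.3 ± 1.02 CPM.

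**Figure D2:**
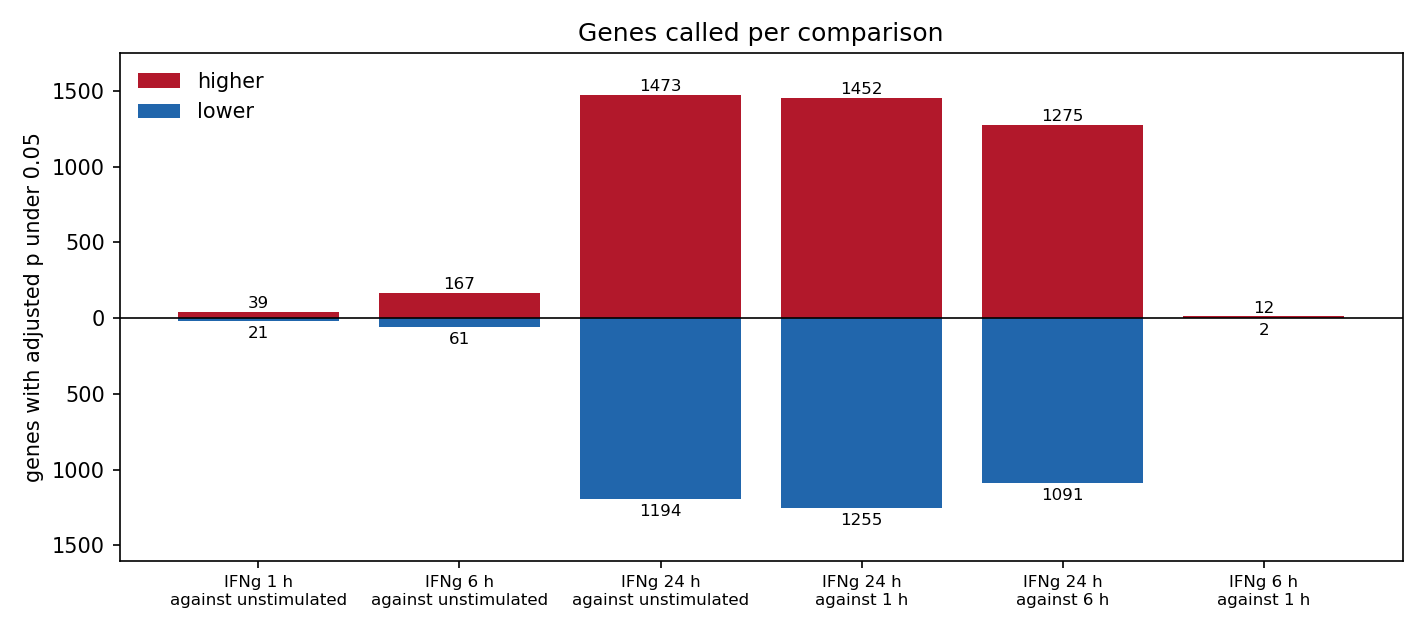
Number of genes with adjusted p under 0.05 that were higher (red, upward) or lower (blue, downward) in each of the 6 comparisons. The bars reach 1473 and 1194 genes for 24 h against unstimulated cells but 39 and 21 for 1 h and 12 and 2 for 6 h against 1 h.

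After a 1 h exposure 5 of 24 MHC class I genes were called above unstimulated cells at harvest and 19 were not called, with a median log2 fold change of 0.022 over the list. H2-K1 (ENSMUSG00000061232.15, chromosome 17, 33996017 to 34000347) was 63.9 ± 2.55 against 45.1 ± 2.71 CPM, a log2 fold change of 0.50 ± 0.05 (adjusted p = 9.59e-07). H2-D1 was 101.5 ± 2.18 against 76.2 ± 6.87 CPM. H2-Q4 rose by 0.68 ± 0.10, B2m by 0.28 ± 0.06 and Nlrc5 by 0.26 ± 0.05. Of the class I genes 0 were called lower (8 higher and 1 lower adjusted over the list alone), and the camera call (adjusted p = 1.05e-07) was lost with an estimated correlation (adjusted p = 0.15) and with fry (adjusted p = 0.0651). Of the 19 lists this was the one called. The call for B2m was lost without unstimulated replicate 1 or 3 (adjusted p = 0.194 and 0.138) or IFNg_1h replicate 1, 2 or 3 (adjusted p = 0.202, 0.0553 and 0.0782). That for Nlrc5 was lost without unstimulated replicate 1 or 3 (adjusted p = 0.0571 and 0.0669) or IFNg_1h replicate 3 (adjusted p = 0.096). Irf1 (adjusted p = 0.969), Cd274 (adjusted p = 0.994) and Ciita (adjusted p = 0.999) were not called, nor was any of the 17 GTPases (1 higher and 1 lower adjusted over the list alone).

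Genes outside the class I list were called after 1 h too, among them H2-Q5 (1.63 ± 0.21 on the log2 scale). Slco1b2, an organic anion transporter, rose by 0.82 ± 0.10 and the sodium pump subunit Atp1b1 by 0.47 ± 0.06, while the linker histone Hist1h1c fell by 0.38 and the chemokine Ccl9 fell by 0.37 on the log2 scale. Slco1b2 and Atp1b1 are among the 92 genes shifted in both blocked arms (closing section). In all 60 genes were called, 39 higher and 21 lower, with 3 at least 2-fold. With the length trend of each library removed, an alternative chosen after seeing the data, the split was 43 higher and 36 lower. Log2 fold changes correlated with exon length across genes, which are not independent replicates (Spearman's rho = 0.258), and with GC content (-0.244). The call for Hist1h1c was lost without IFNg_1h replicate 1 (adjusted p = 0.0689). The count was 15 without unstimulated replicate 1, 21 without unstimulated replicate 3, 114 without unstimulated replicate 2, 22 without IFNg_1h replicate 1 and 21 without IFNg_1h replicate 3.

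A 6 h exposure left more class I transcript. GTPase transcripts were counted at low levels (for Gbp2, Iigp1, Tgtp2 and Gbp7 see the closing section). H2-Q7 was 0.492 ± 0.152 against 0.0574 ± 0.0550 CPM (adjusted p = 6e-04) and H2-Q6 1.69 ± 0.230 against 0.343 ± 0.158 CPM (adjusted p = 6.49e-06). H2-K1, chosen after its value was seen, was 101.0 ± 2.63 CPM, 1.16 ± 0.05 above unstimulated cells on the log2 scale (adjusted p = 1.01e-15). B2m rose by 0.60 ± 0.06 and Nlrc5 by 0.45 ± 0.05. Class I genes rose in 9 of 24 members (11 and 2 adjusted over the list alone; camera adjusted p = 0.000421 with an estimated correlation), and the 1 that fell was Pdia3 (-0.18 ± 0.04, chosen after its value was seen). GTPases rose in 7 of 17 (8 and 1 adjusted over the list alone; camera adjusted p = 0.000421 with an estimated correlation). The call for Tgtp2 was lost in 4 of the 6 fits that left out a library (adjusted p = 0.176 without unstimulated replicate 1). Gbp2 was 1.55 ± 0.181 against 0.346 ± 0.127 CPM, and Iigp1 had 68 counts over the 3 libraries against 2 (adjusted p = 0.0042), which is 0.0401% of its count after 24 h. Antiviral genes rose in 4 of 36 (4 adjusted over the list alone; camera adjusted p = 0.0378 with an estimated correlation). Slfn8 rose by 0.62 ± 0.09, Samhd1 by 0.19 ± 0.04, Cmpk2 by 1.06 ± 0.28 and Parp14 by 0.24 ± 0.06. The last 3 calls depended on single libraries: without unstimulated replicate 1 the adjusted p was 0.0818 for Samhd1, 0.255 for Cmpk2 and 0.231 for Parp14. They were lost in 2, 4 and 4 of the 6 fits that left out a library. Irf1 (12.1 ± 0.579 CPM, adjusted p = 0.109), Socs1 (adjusted p = 0.054) and Cd274 (adjusted p = 0.209) were not called.

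The lists called lower after 6 h did not hold with an estimated correlation: MYC targets (1 of 32 called, Ldha, at -0.18 ± 0.04; adjusted p = 0.297), the integrated stress response (Atf4 at -0.18 ± 0.05; adjusted p = 0.26) and housekeeping genes (Pgk1 at -0.35 ± 0.06 and Gapdh at -0.17 ± 0.04; adjusted p = 0.139). MHC class II genes, 1 of 15 called (H2-Ob at 0.24 ± 0.05), and mitochondrial transcripts, 0 of 15 called, were called higher and likewise lost the call (adjusted p = 0.054 and adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone, 1 MYC target, 2 stress response and 2 housekeeping genes were lower, 5 class II genes were higher and 0 mitochondrial transcripts passed. With fry, housekeeping genes (adjusted p = 0.0445) and class II genes (0.00393) kept the call. MYC targets (0.0652), the stress response (0.0593) and mitochondrial transcripts (0.34) lost it with fry. Without unstimulated replicate 1 the calls for Ldha (adjusted p = 0.158), Atf4 (0.168), Gapdh (0.249) and H2-Ob (0.187) were lost, and each was lost in 3 to 5 of the 6 fits that left out a library. Of the p53 list Trp53inp1 and Btg2 rose (0.26 ± 0.05 and 0.21 ± 0.04; 4 higher and 1 lower adjusted over the list alone), and of B cell genes Ebf1 rose and Spib fell (0.32 ± 0.05 and -0.20 ± 0.04; 1 higher and 2 lower adjusted over the list alone). The calls for Trp53inp1 (adjusted p = 0.0553), Btg2 (0.0515) and Spib (0.0608) were lost without unstimulated replicate 1. Hist1h1c fell by 0.71, the scavenger receptor Cd36 by 0.54 and the heme oxygenase Hmox1 by 0.42 on the log2 scale. Pdia3, Ebf1, Spib and Cd36 are also among the 92 genes shifted in both blocked arms. The total was 228 genes, 167 higher and 61 lower. Log2 fold changes correlated with exon length across genes (Spearman's rho = 0.259) and with GC content (-0.242). Between exposures the values for GC content were -0.062 (24 h against 1 h), -0.044 (24 h against 6 h) and -0.041 (6 h against 1 h). Those for exon length were -0.05, -0.081 and 0.046. The count was 531 without IFNg_6h replicate 3, 89 without unstimulated replicate 1, 124 without unstimulated replicate 3, 130 without IFNg_6h replicate 1 and 94 without IFNg_6h replicate 2.

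**Figure D3:**
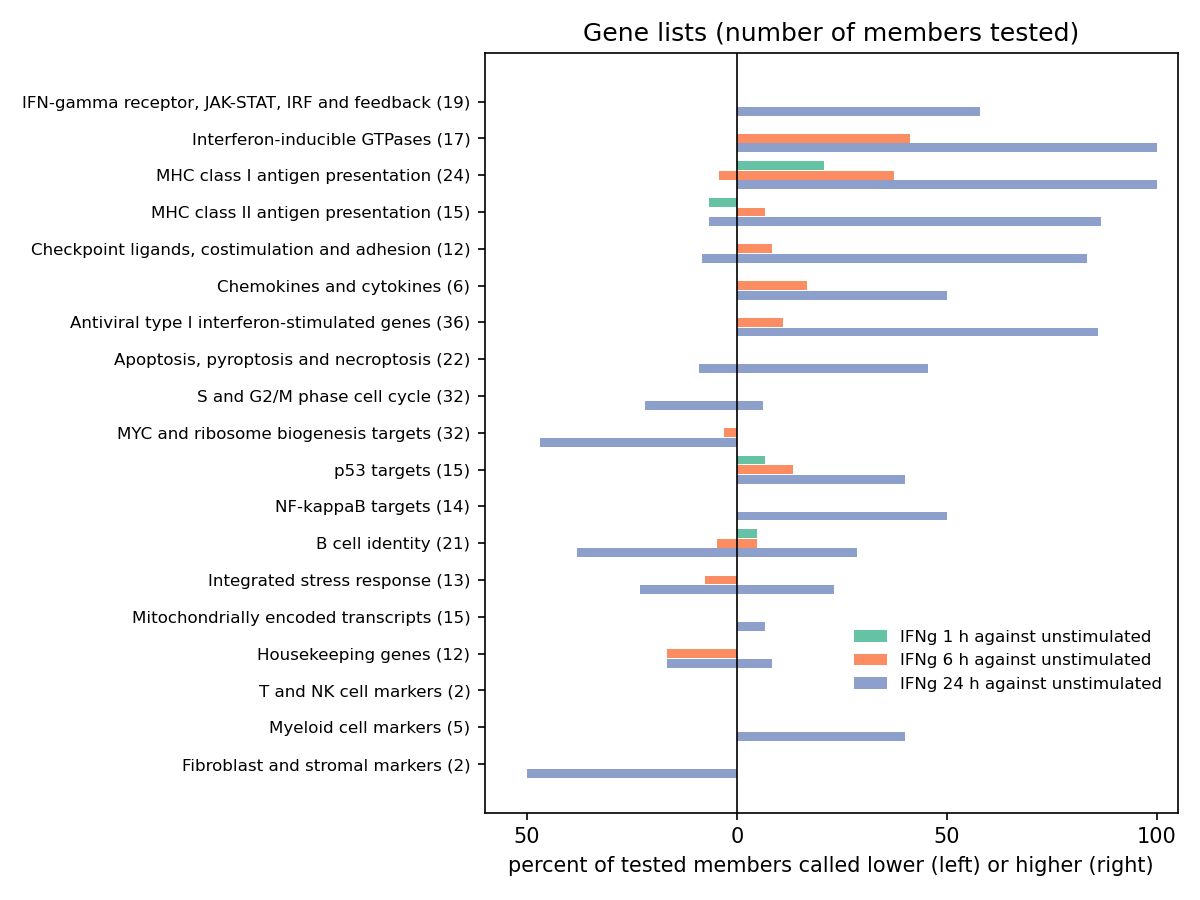
Percent of the tested members of each of the 19 fixed gene lists called lower (left of 0) or higher (right of 0) against unstimulated cells after 1 h, 6 h and 24 h of IFN-γ, with the number of members tested in parentheses. GTPases have 0 of 17 members higher after 1 h, 7 after 6 h and 17 after 24 h.

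Exposures were then compared with one another. Between 6 h and 1 h, 14 genes were called. H2-K1 (0.66 ± 0.05), H2-Q4 (0.69 ± 0.09), H2-D1 (0.45 ± 0.05), the peptide transporter Tap1 (0.36 ± 0.06), B2m (0.33 ± 0.06), the thiol reductase Ifi30 (0.31 ± 0.05), Gbp2 (1.30 ± 0.15), Ifi47 (0.68 ± 0.14), Gbp3 (0.37 ± 0.07) and Col27a1 (0.51 ± 0.08) were higher after 6 h, with the predicted genes Gm4070 and Gm1966 (1.68 and 0.59, chosen after their values were seen). Hist1h1c (-0.33 ± 0.07) and the glycolytic enzyme Aldoa (-0.25 ± 0.05) were lower. In the fits that left out 1 library the calls for Gbp3 (adjusted p up to 0.3, without IFNg_1h replicate 1), Ifi47 (0.294, without IFNg_1h replicate 3), Hist1h1c (0.302, without IFNg_1h replicate 2), Aldoa (0.197, without IFNg_1h replicate 2), B2m (0.151, without IFNg_1h replicate 3), Ifi30 (0.0912), Col27a1 (0.0589) and Tap1 (0.0547, these 3 without IFNg_1h replicate 1) were lost. The count was 24 without IFNg_6h replicate 3, 9 without IFNg_1h replicate 1, 8 without IFNg_1h replicate 2 and 8 without IFNg_1h replicate 3. GTPase (3 of 17) and class I genes (5 of 24) rose as lists, with 9 and 12 adjusted over the list alone (camera adjusted p = 8.45e-05 and 0.000874 with an estimated correlation). Lists with 0 or 1 called member also shifted upward: receptor and feedback genes (adjusted p = 0.0264 with an estimated correlation), class II genes (0.00761), checkpoint genes (0.0346) and antiviral genes (0.000874), with 3, 2, 0 and 5 members higher adjusted over the list alone. MYC targets, called lower, B cell genes and NF-κB targets, called higher, and T and NK markers, called lower, lost the call (adjusted p = 0.11, 0.119, 0.0548 and 0.117 with an estimated correlation). With fry, NF-κB targets kept it (adjusted p = 0.0479). MYC targets (0.0547), B cell genes (0.101) and T and NK markers (0.132) did not.

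Against 1 h, the 24 h libraries had 1452 genes higher and 1255 lower, and against 6 h, 1275 higher and 1091 lower. The class I and GTPase lists were higher in every tested member in both comparisons (24 of 24 and 17 of 17, also adjusted over the list alone). Irf1 was 4.40 ± 0.06 above 1 h and 4.19 ± 0.06 above 6 h, and Cd274 3.34 ± 0.10 and 3.06 ± 0.10. Tap1 was 136.5 ± 3.60 CPM after 24 h, 24.6 ± 1.13 after 6 h and 19.2 ± 1.31 after 1 h. The proliferation marker Mki67 was lower after 24 h than after 1 h (-0.33 ± 0.05) and 6 h (-0.30 ± 0.05), but it is also 1 of the 92 genes shifted in both blocked arms (0.18 above unstimulated cells on the log2 scale). The cell cycle list was not called by camera (adjusted p = 0.0723 and 0.169) but was called lower by fry (adjusted p = 0.000213 and 0.00179). It had 2 and 3 members higher and 8 and 7 lower (2 and 4 higher, 10 and 10 lower adjusted over the list alone).

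Calls overlapped between exposures. Of 39 genes higher after 1 h, 34 were higher after 6 h, where independent lists would share 0.46. Of the 39, 27 were higher after 24 h, where they would share 4.02. Of the genes lower, 10 were shared by 1 h and 6 h against 0.09, 5 by 1 h and 24 h against 1.75 and 31 by 6 h and 24 h against 5.09. Of 167 genes higher after 6 h, 104 were higher after 24 h against 17.2. The covariance of the 6 h and 24 h fold changes was 0.1083 against a simulated 0.03064 (correlation 0.472 against 0.504), and of 1 h and 6 h 0.05747 against 0.03081 (correlation 0.591 against 0.505). For 1 h and 24 h it was 0.06297 against 0.03069 (correlation 0.306 against 0.509). The simulated groups hold no change, whereas genes changed only after 24 h widen the real 24 h fold changes and lower the correlation. A correlation below the simulated one is therefore not read as agreement below chance. Part of the overlap can come from the shared control libraries, which could not be split. Overlap of 1 h with 6 h can also come from antibody or handling in both blocked arms.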

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

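The tests of carry-over, library complexity, depth and the change left by the corrections were chosen after the result was seen. The length and GC corrections were chosen after the uncorrected data were seen, but their bounds for genes past both tests were set before the corrected result was. The tests of antibody and other splits of the samples were fixed before their result. Each effect against unstimulated cells was compared with the others by testing the exposures directly (edgeR adjusted p). The effects of 24 h and 1 h differed for 2707 genes, those of 24 h and 6 h for 2366, and those of 6 h and 1 h for 14. The labels do not say whether 24 h samples received antibody. Antibody or handling can therefore contribute to calls of 24 h against 1 h or 6 h, here and above. Some genes were called in opposite directions: 8 after 1 h and 24 h, and 20 after 6 h and 24 h, where independent lists would give 5.42 and 20.22. The lists are not independent, since the shared control libraries move both fold changes the same way. These values can thus be too high as an expectation, and whether opposite calls exceed chance cannot be told from them.

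With 1 h and 6 h averaged, 238 genes were called against unstimulated cells. Of these, 92 genes (54 higher and 38 lower) differed in the same direction from both unstimulated and 24 h cells, such as Atp1b1, at 67.3 ± 4.21 CPM after 1 h, 67.2 ± 4.95 after 6 h, 48.5 ± 1.41 in unstimulated cells and 30.6 ± 0.804 after 24 h (SD, n = 3). Both tests use the same blocked libraries, so a deviation of those libraries moves a gene alike in both. How many genes this alone would give was not computed. A smooth GC trend alone is argued against. With the GC trend removed, 89.1% of the 92 passed both tests (95% interval 81.1 to 94.0%, bound set beforehand 75%). A smooth length trend as the whole cause is argued against too. Each correction removed an average trend per library, and the length and GC trends were not removed together. A bias of single genes, or of length and GC jointly, stays open. With the length trend removed, the 92 genes kept a median of 94.5% of their difference from unstimulated cells (bootstrap 95% interval 91.5 to 96.7%) and 98.1% of that from 24 h cells (95.6 to 99.3%). The median absolute log2 change was 0.227 before and 0.221 after, and 101 genes passed both tests. Of the 92, 78.3% passed, but the interval of 68.8 to 85.5% spans the bound, and in single genes as little as 32.8% was left. All these intervals take genes as independent, which they are not, and leave out the spread between samples. The weighing of GC and length therefore covers these libraries only. In the 20 that failed, the median change from unstimulated cells went from 0.201 (quartiles 0.149 to 0.229) to 0.138 (0.118 to 0.193). That from 24 h cells went from 0.247 (0.161 to 0.372) to 0.226 (0.105 to 0.342). Their median adjusted p against unstimulated cells was 0.0376 before and 0.0781 after, so calls near the threshold ended as the change shrank, and a contribution of length stays open for them. Genes higher in the pattern had a median exon length of 6277 bases against 3709 for all genes. Antibody or handling in both blocked arms also stays open for the 92 genes, because no sample is labelled as antibody alone. For the same reason it stays open for every other call of 1 h or 6 h against unstimulated cells, with 1 limit. An effect equal in both blocked arms would cancel between 6 h and 1 h. There the class I list was higher, with 5 of 24 members called (camera adjusted p = 0.000874 with an estimated correlation). This argues against an equal effect as the whole cause of the 6 h rise of that list. The antibody was added at different times, so an unequal effect stays open.

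IFNg_6h replicate 3 stood apart on the second principal component. Lower depth as the whole cause is argued against, since its total of 53.22 M counts (M, mega) exceeds the 49.44 M of unstimulated replicate 2, which did not stand apart. Its total was below that of every other library, so a contribution of depth stays open. At equal depth IFNg_6h replicate 3 had 17560 detected genes, fewer than in each of the other 11 libraries (17667 to 18124). Lower library complexity may therefore contribute, although a gap this small is weak evidence and 1 of 12 libraries must be lowest. No biological explanation was tested.

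Transcripts above unstimulated cells after a 6 h exposure could be reads carried over from 24 h libraries. For the 104 genes called higher after both exposures this is argued against as the whole cause: the lower quartile of the 6 h excess was 21.7% of the 24 h excess, above the 0.0714% that 9 genes near 0 in unstimulated cells allow. Iigp1 gives 71.5% of the 24 h reads of those 9, and without it the limit is 0.126%, which is used from here on. Of the 7 GTPases called after 6 h, 3 exceeded it even by the lowest 6 h library minus the highest unstimulated one: Gbp3 (0.399%), Ifi47 (0.275%) and Gvin1 (1.13%). For the other 4 carry-over cannot be told apart from low expression: Gbp2 (0.0946%), Tgtp2 (0.0138%) and Gbp7 (-0.00468%) lay under the limit, and Iigp1 is itself 1 of the 9. All 7 are given, of which Gbp3, Ifi47, Gvin1 and Gbp7 were chosen after their values were seen. For the 9 genes near 0, Iigp1 and Gbp4 among them, carry-over cannot be told apart from low expression. These 9 genes had 61 read pairs in the 6 h libraries and 16 in the 1 h libraries. To be the whole cause of the 6 h excess, carry-over would have to be uneven between these groups, which was not tested. A plain chi-square test rejected one common ratio (p = 1e-04, the smallest that 10000 simulated tables can give), but it ignores the genes' own unstimulated level, and with that level allowed for a common ratio was not rejected (p = 0.072, 1000 simulated tables).

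Each count of calls was set beside the other splits of its 6 libraries into 3 and 3; with the real one there are 10, too few for a share under 0.05. The real split gave 60 genes for 1 h against unstimulated cells and the highest other split 21 (1 split as large, the real one). For 6 h, 2 splits were as large: the real one gave 228 and the highest other 231, from unstimulated replicates 1 and 3 with IFNg_6h replicate 3 against unstimulated replicate 2 with the other two 6 h libraries, which points to a structure of these libraries besides treatment. For 24 h the real split gave 2667 and the highest other 0; against 1 h 2707 and 1, against 6 h 2366 and 0, and for 6 h against 1 h 14 and 2.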

How the results depend on the processing

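Halved counts and the length and GC corrections were chosen after seeing the data. No called gene that the naming rule took changed sign under any alternative in which it was tested. Genes named outside the rule were not part of this check. With RLE factors, halved counts or either correction each count of calls stayed within 1.5 times its value. The order of values below is 1 h, 6 h and 24 h against unstimulated cells, then 24 h against 1 h, 24 h against 6 h and 6 h against 1 h, where all are given; the cause was not tested, except that stricter thresholds call fewer genes and left-out libraries leave fewer samples by construction. A fold of at least 2 left 3, 21, 381, 373, 336 and 2 genes, and an adjusted p under 0.01 left 21, 80, 1562, 1650, 1403 and 8. With a filter of 1 count in any library, 174, 413 and (6 h against 1 h) 36 genes were called, with DESeq2 119, 374 and 35, and with the 6 libraries compared 104, 95 and 9. Limma-voom called 38 genes for 1 h and 9 for 6 h against 1 h. Leaving out each library in turn gave 15 to 114, 89 to 531, 1816 to 2520, 1893 to 2201, 1682 to 2798 and 8 to 24.

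Samples with the same replicate number did not consistently deviate together: only 8 of 18 same-number correlations exceeded 0.1, from -0.35 to 0.281. With the replicate number as a block, 78, 265, 2746, 2790, 2480 and 16 genes were called, and no gene list changed its call. With an estimated correlation the number of lists called went from 1 to 0 (1 h), 8 to 3 (6 h), 11 to 7 (24 h), 11 to 7 (24 h against 1 h) and 10 to 6 (6 h against 1 h). With fry it was 0 for 1 h, 5 for 6 h, 14 for 24 h and for 24 h against 1 h and against 6 h (where camera called 9), and 7 for 6 h against 1 h, and with the length trend removed 2 for 1 h. Over genes with a mean of at least 10 CPM the covariances were 0.00926 (1 h and 6 h), 0.01498 (1 h and 24 h) and 0.04629 (6 h and 24 h), with simulated values of 0.002713, 0.002732 and 0.00268. The correlations were 0.716, 0.306 and 0.627 against a simulated 0.503, 0.51 and 0.506, so that of 6 h and 24 h lay above the simulated one here and below it over all genes (0.472 against 0.504). With 24 h, a value below the simulated one is not read as agreement below chance, because the simulated groups hold no change. Depth limits genes with a few counts, for which a fold is given only as a bound or with its counting interval.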

Other observations

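The stress transcription factor Atf3 rose from 1.17 ± 0.249 to 5.65 ± 0.574 CPM after 24 h of IFN-γ (SD, n = 3), and the integrated stress response list had 3 members higher and 3 lower of 13 by edgeR adjusted p (3 and 3 adjusted over the list alone; camera adjusted p = 0.739). The other members called, chosen after their values were seen except Ddit3, were Ddit3 (0.50) and Ppp1r15a (0.31), higher, and Slc7a5 (-0.29), Psat1 (-0.19) and Shmt2 (-0.16), lower, on the log2 scale. The call for Ddit3 was lost without unstimulated replicate 3 (adjusted p = 0.0596). Of 6 tested chemokine and cytokine genes, of 24 in the list, 3 rose (3 adjusted over the list alone). The list was called higher by fry (adjusted p = 0.000596) but was not called by camera (adjusted p = 0.267). Tnfsf10, which encodes the death ligand TRAIL, rose from 0.199 ± 0.0741 to 1.20 ± 0.166 CPM and Cxcl10 from 0.0586 ± 0.0545 to 0.373 ± 0.121 CPM. The other was Ccl3, whose call was lost in 5 of the 6 fits that left out a library (adjusted p = 0.17 without unstimulated replicate 1).

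Cell cycle genes had 2 members higher and 7 lower of 32 after 24 h (3 and 10 adjusted over the list alone), with Mcm3 at -0.26 ± 0.04. The list was called lower by fry (adjusted p = 0.000596) but was not called by camera (adjusted p = 0.114). The 2 higher members, chosen after their values were seen, were Top2a (0.24) and Bub1 (0.13). Of 2 fibroblast markers tested Fn1 fell, at 0.360 ± 0.0797 against 0.729 ± 0.273 CPM (1 adjusted over the list alone; camera adjusted p = 0.698), but not without unstimulated replicate 1 (adjusted p = 0.293), IFNg_24h replicate 1 (0.1) or IFNg_24h replicate 2 (0.134). Of 12 housekeeping genes 1 rose and 2 fell, Pgk1 and Gapdh (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.6). Without unstimulated replicate 1 the calls for Pgk1 (adjusted p = 0.163) and Gapdh (adjusted p = 0.067) were lost. Of 15 mitochondrial transcripts mt-Rnr1 rose, by 0.33 ± 0.08 (1 adjusted over the list alone; camera adjusted p = 0.267), but not without IFNg_24h replicate 1 (adjusted p = 0.0532) or IFNg_24h replicate 3 (adjusted p = 0.0576).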
